A study of Homo sapiens with 3 samples.

How the data were processed

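RNA-seq was performed on 3 libraries of A375-PPAP2.2 cells, 1 per group: a control at 0 h and cells after 6 h and 24 h of blue light. Per the labels' protocols, total RNA was extracted with a column kit and made into stranded libraries with the TruSeq kit, and the serum was lowered to 1% 3 h before the light. Whether the libraries came from separate cultures is not given in the sources used here. The column code of the 24 h library ends in 26, while its title and its time label say 24 hours, and the labels were followed.

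Per the submitters' processing notes, Trimmomatic, HISAT2 2.1.0, StringTie 2.1.3b and GRCh38 were used, with no role or order stated. The authors deposited, for 19634 genes with NCBI Gene IDs, a read count, an FPKM and a TPM value per library. Every listed gene had at least 1 read in each library, so a gene with no reads in even 1 library is not listed and was not analysed here. A gene read in 1 library and silent in another therefore could not be called. The listed genes' TPM summed to 999017, 999057 and 998955. The authors also deposited normalized log2 values, which differed by at most 5e-09 from log2(CPM + 1) with TMM factors. For each light time against 0 h the authors deposited a signed fold change (a score that is negative for a lower value), a mean log2 CPM, and raw and adjusted p-values. The deposited raw p-values differed by at most 3.44e-15 from edgeR's exact test with an assumed biological coefficient of variation of 0.4, and by 0.112 or more with 0.2, 0.3 or 0.5. They are given only as the authors' own. All columns of per-sample values could be tied to a library.

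Total counts were 37320189, 38596210 and 43865361. TMM factors from edgeR 4.0.16 in R 4.3.3 were 0.9997, 0.9842 and 1.0163. The log2 ratio of 2 libraries was computed from CPM on the effective library sizes with 0.5 CPM added, which understates the change of low genes. A gene was called higher or lower when the ratio was at least 2-fold, the mean over the 3 libraries at least 1 CPM, and the 95% exact (Clopper-Pearson) counting interval excluded a ratio of 1. Ratios given beside intervals are of CPM without the added 0.5. With 1 library per group no test across libraries is possible. The rule describes these libraries and not the conditions.

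Before the data were examined, 33 gene lists, the size rule, the alternatives and the rule for named genes were fixed. Named were the 10 genes with the largest ratio in each direction at each time against 0 h (5 for 24 h against 6 h) with a mean of at least 5 CPM, leaving out uncharacterized loci and small RNAs. Added to these were up to 4 members per list with the largest absolute ratio and 10 genes fixed by name, of which 1 is not reported here. Because readthrough genes filled much of this ranking, the same ranking without readthrough genes and their components was added after the data were seen. Through it alone MALAT1, CENPP, FLJ37453, NBPF6, TIPARP, VIPR1, ADGRF1, INHBE, PIGY and TNFSF14 are named. CYP1A1 was also chosen after its values were seen. Each list's median log2 ratio was placed among 10000 random lists of equal size matched on mean expression in 20 bins. A list was called apart below percentile 2.5 or above 97.5, with at least 5 measured members. Members of a list are regulated together, so the percentiles describe these libraries only. The ratios and list medians were looked at once before the full computation was set up.

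The lists without a call against 0 h were as follows. Glycolysis had medians of 0.06 at 6 h and 0.01 at 24 h, fatty acid synthesis 0.01 and 0.04, and lysosome and autophagy -0.01 and 0.05. p53 targets stood at -0.05 and 0.07, the latter at percentile 94.4 and, with length and GC matching, at 98.0, past the limit. The interferon response stood at 0.02 and 0.10, and the melanocyte lineage at -0.03 and 0.07. YAP and SRF targets stood at -0.01 and 0.06, the extracellular matrix at 0.03 and 0.04, oxidative stress genes at -0.04 and -0.04, and keratinocyte markers at -0.03 and -0.06. The 4 measured blood and endothelium markers had medians of 0.19 and 0.04 and no percentile.

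Alternatives were DESeq2 1.42.0 size factors, plain CPM, no expression filter, a mean of at least 5 CPM, pseudocounts of 0.1 and 2, 1.5-fold and 3-fold limits, and deposited FPKM and TPM with a pseudocount of 1 and no counting interval. Added after the data were seen were leaving out readthrough genes with their components, summing them into 1 locus, and random lists matched on expression, transcript length and GC content (100 nearest genes per member). The gene drawn for a member could be that member or another of its list, so these random lists can partly restate the list. Transcript length was computed from deposited counts and FPKM, and GC content from GENCODE v29 transcripts, for 13507 genes. Coordinates are from RefSeq on GRCh38.p14, in which 19295 of the Gene IDs were found. XIST and Y-linked genes were left out of the gene tables.

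The size rule was tested on simulated data with 200 changed genes among 14477 and counting noise alone, with no variation between libraries. For 6 h against 0 h it found 90% of 2.5-fold, 96% of 4-fold and 0% of 1.5-fold changes, and for 24 h 82%, 98% and 0%, with 0 unchanged genes called under that noise. In 20 simulated sets without change, a coefficient of variation between libraries of 0 gave 0 genes at 6 h, 0.1 gave 0.3, 0.2 gave 199 and 0.4 gave 3022. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.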

Results

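The data describe gene expression in A375-PPAP2.2 cells, a derivative of the human melanoma line A375 that carries PPAP2.2, in a series on optogenetic hyperactivation of PI3K signaling and cancer drug resistance. PI3K is a lipid kinase that activates AKT and mTOR downstream of growth factor receptors, and optogenetic tools switch a signaling protein on with light. Blue light was given for 6 h or 24 h, and a control was taken at 0 h. Each of these 3 groups had 1 library, so no comparison has a replicate check and no p-value was used to call a difference. The deposited read counts of the 19634 listed genes summed to 37320189 at 0 h, 38596210 at 6 h and 43865361 at 24 h. The cells were moved from medium with 10% serum to medium with 1% serum 3 h before the light. If the control was taken as the light began, the libraries came after 3, 9 and 27 h in reduced serum, and no dark library of 9 or 27 h was analysed here. A difference between libraries therefore cannot be assigned to light rather than to time in reduced serum.

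Most transcripts stayed close to their 0 h level. Of 14477 genes with a mean of at least 1 CPM (read counts scaled by library size, with TMM factors), 96.6% lay within 1.5-fold of the 0 h library at 6 h and 96.8% at 24 h. At least 2-fold differences were found for 36 genes higher and 43 lower at 6 h, and for 55 higher and 21 lower at 24 h. Between the lit libraries, 69 genes were higher and 28 lower at 24 h than at 6 h. With deposited FPKM the balance differed, with 15 genes higher and 34 lower at 6 h, 22 and 23 at 24 h, and 18 and 13 at 24 h against 6 h. The spread of the log2 ratio over the 4666 genes with a mean of at least 50 CPM, as a robust SD, was 0.13 at 6 h and 0.17 at 24 h. Ranges given after ratios are 95% exact (Clopper-Pearson) counting intervals, which cover counting error only. Variation between cultures was not measured. In unchanged simulated libraries, a coefficient of variation between libraries of 0.1 gave a mean of 0.3 genes past the rule at 6 h. A value of 0.2 gave 199, more than were observed, so 0.2 in every gene would be too large here. Variation of that size in some of the genes was not excluded.

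**Figure D1:**
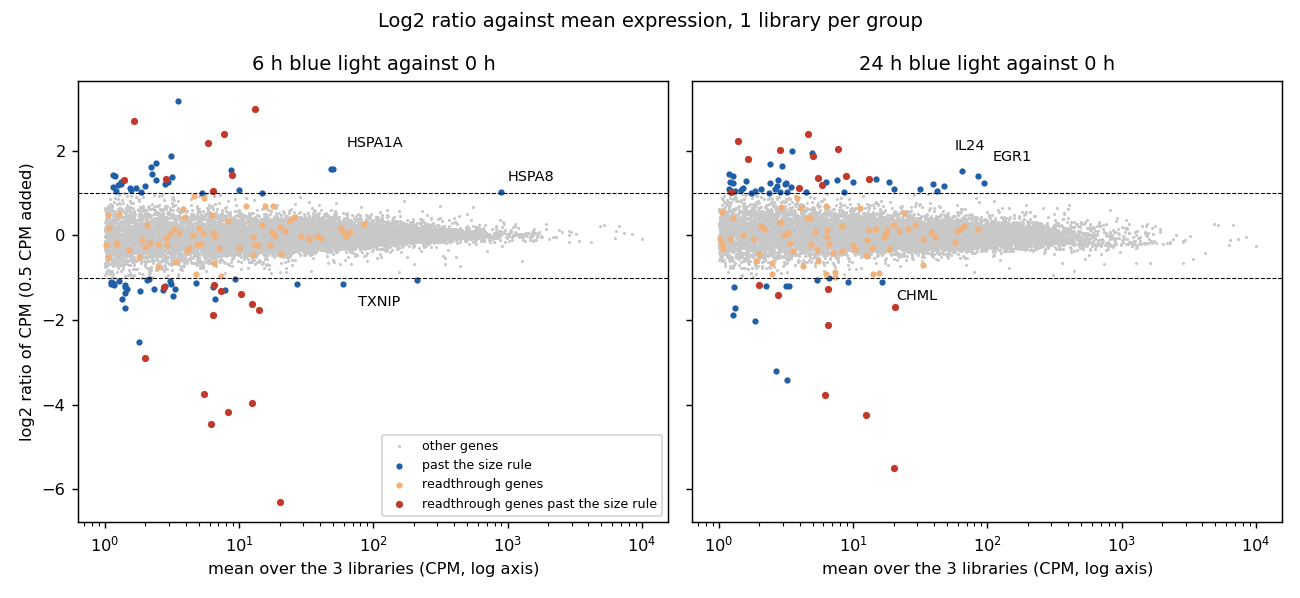
Each point is 1 gene, with its mean over the 3 libraries in CPM on a log axis and its log2 ratio to the 0 h library, for 6 h and 24 h of blue light. The dashed lines mark 2-fold. Readthrough genes, which span a pair of neighbouring genes, made up 8 of the 36 higher and 13 of the 43 lower genes at 6 h, and 12 of the 55 and 8 of the 21 at 24 h, and took the lowest value in both panels (BLOC1S5-TXNDC5, -6.30 and -5.50).

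The first comparison asked how the transcriptome looked after 6 h of light against 0 h. The 3 genes with the highest mean CPM among those at least 2-fold higher encode HSP70-family heat shock proteins. HSPA1A (Gene ID 3303, GRCh38 chromosome 6, 31815543 to 31817942), an inducible HSP70 chaperone, went from 27.9 to 84.3 CPM, a ratio of 3.02 (2.82 to 3.25). Its near-identical neighbour HSPA1B (Gene ID 3304, chromosome 6, 31827738 to 31830254) went from 1008 to 3094 reads, a ratio of 3.02 (2.81 to 3.24). Reads of this pair can be split arbitrarily in counting, so their sum was also taken, and it gave a ratio of 3.02 (2.87 to 3.18). HSPA8 (Gene ID 3312, chromosome 11, 123057489 to 123062462), the constitutive HSC70, went from 651 to 1331 CPM, a ratio of 2.05 (2.01 to 2.08). DNAJA1, an HSP40 co-chaperone, stood at 136 and 239 CPM, below the 2-fold limit at 1.75 (1.69 to 1.81). In the list of heat shock and ER chaperones, 22 of 30 measured members were above their 0 h level and 3 passed the size rule. Its median log2 ratio of 0.09 lay at percentile 99.0 of 10000 random lists matched on mean expression.

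Among genes at least 2-fold lower at 6 h, TXNIP (Gene ID 10628, chromosome 1, 145992435 to 145996579), an arrestin-family protein that restrains glucose uptake, went from 57.9 to 25.9 CPM, a ratio of 0.447 (0.414 to 0.482). It is a member of the list of targets of FOXO, the transcription factors that AKT keeps out of the nucleus. Of 24 measured FOXO targets 19 were below their 0 h level, with a median log2 ratio of -0.26 and a percentile of 0.0 among random lists. TXNIP alone passed the size rule. GADD45A stood at -0.49, YPEL3 at -0.42 and KLF15, close to the expression limit with 43 and 25 reads, at -0.51. MALAT1 (Gene ID 378938, chromosome 11, 65497738 to 65506516), a nuclear long non-coding RNA, went from 275 to 133 CPM, a ratio of 0.482 (0.466 to 0.498). Lower by the same rule were CCDC144NL (log2 ratio -1.50), COL1A1 (-1.29), which encodes a collagen chain, FLJ37453 (-1.22) and CENPP (-1.02), a centromere protein gene. NBPF6 was higher, at 1.01. COL1A1 belongs to the list of fibroblast markers, whose 7 measured members had a median of -0.32 (percentile 0.76). FAP stood at 2.76 and 1.71 CPM and POSTN at 1.45 and 0.684, close to the expression limit, and the call was lost at a mean of at least 5 CPM and with FPKM or TPM.

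Inflammatory cytokines and mitotic genes were also lower at 6 h, without passing 2-fold. In the NF-kB and cytokine list 23 of 27 members were below their 0 h level, with a median log2 ratio of -0.26 (percentile 0.0). CXCL8, a neutrophil chemokine, went from 1660 to 1095 CPM, CXCL1 from 610 to 369 and IL6 from 38.4 to 21.1. In the G2/M and mitosis list 30 of 33 members were below, with a median of -0.15 (percentile 0.0), including CDC25C (-0.42), BIRC5 (-0.33) and CDK1 (-0.27). The ERK output list, genes induced by MAP kinase signaling, had 19 of 24 members above 0 and a median of 0.14 (percentile 99.95). None of them passed the size rule. SPRY4 stood at 0.48, EPHA4 at 0.48 and DUSP4 at 0.46. The list of PI3K-AKT-mTOR components had a median of 0.10 (percentile 99.4), and lay at percentile 89.0 against random lists also matched on transcript length and GC content. PDPK1 stood at 0.41, GRB10 at 0.39 and EIF4EBP2 at 0.36.

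Of the 32 lists with a percentile, 13 lay outside the central 95% of random lists at 6 h, 3 above and 10 below, where 1.6 would be outside by chance if genes were independent. The other 6 below were as follows. Circadian clock genes had a median of -0.12 (percentile 1.60, a call lost with no expression filter, FPKM or TPM), with PER1 at -0.54 and DBP at -0.49. Mitochondrially encoded transcripts stood at -0.10 (0.08), cholesterol synthesis genes at -0.07 (0.29) and 6 replication-dependent histone genes at -0.33 (1.18, a call lost at a mean of at least 5 CPM). Respiratory chain genes of the nucleus (-0.04, percentile 0.80) and ribosomal protein genes (-0.03, percentile 0.30) lost the call with FPKM and TPM. They also lost it with length and GC matching, at percentiles 9.86 and 8.52. The matched lists could draw members of the same list. Longer transcripts had higher ratios, with a Spearman rho of 0.26 across 13507 genes, which are not independent replicates.

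The comparison of 24 h of light with 0 h showed the cytokine IL24 and the immediate early genes EGR1 and JUN at least 2-fold higher. IL24 (Gene ID 11009, chromosome 1, 206897443 to 206904139), a cytokine of the IL-10 family, went from 40.7 to 118 CPM, a ratio of 2.88 (2.72 to 3.06). EGR1 (Gene ID 1958, chromosome 5, 138465479 to 138469303), an immediate early transcription factor, went from 58.4 to 156 CPM, a ratio of 2.67 (2.55 to 2.81). JUN went from 30.6 to 69.6 CPM. In the immediate early list 24 of 29 members were above 0, with a median log2 ratio of 0.23 (percentile 100), and EGR1 and JUN passed the size rule. FOSL1 stood at 0.72 and ATF3 at 0.69.

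ATF4 targets, which supply amino acids and respond to stress, were above their 0 h level as a list. Of 35 measured members 31 were above 0, with a median of 0.24 (percentile 100). GDF15, a stress-induced cytokine, went from 12.8 to 31.4 CPM, from 479 to 1400 reads, a ratio of 2.45, and alone passed the size rule; it is also on the p53 list. ALDH1L2 stood at 0.88, STC2 at 0.79 and ATF3 at 0.69. Aminoacyl-tRNA synthetases had a median of 0.10 (percentile 99.6), with 12 of 20 members above 0 and WARS1 at 0.29. In the hypoxia list 17 of 23 members were above, with a median of 0.16 (percentile 99.96). ANGPTL4, a secreted inhibitor of lipoprotein lipase, passed the rule at 1.22, while NDRG1 stood at 0.55 and VEGFA at 0.52. Single genes past the rule were CYP1B1, a cytochrome P450 (log2 ratio 1.27, 3.97 to 10.3 CPM), TIPARP (Gene ID 25976, chromosome 3, 156674590 to 156706770; 62.9 to 150 CPM), LINC01239 (1.32), VIPR1 (1.10) and ADGRF1 (1.04).

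Genes of DNA replication, translation and respiration were lower at 24 h as groups, with no member past 2-fold. All 34 measured members of the G1/S and replication list were below their 0 h level, with a median log2 ratio of -0.32 (percentile 0.0), and PCNA, the replication clamp, went from 142 to 95.2 CPM. E2F2 stood at -0.58, POLE2 at -0.56 and E2F1 at -0.53. In the G2/M list 30 of 33 members were below, with a median of -0.17 (0.0). Of 67 ribosomal protein and translation factor genes 65 were below, with a median of -0.20 (0.0), RPL24 going from 579 to 463 CPM. Nuclear respiratory chain genes had a median of -0.20 with 28 of 30 members below, and ribosome biogenesis genes -0.13 with 25 of 30 below. The 13 mitochondrially encoded transcripts had a median of -0.55 with 11 below, and their share of the counted reads was 3.81% at 0 h and 3.13% at 24 h. Random lists matched on length and GC content as well had medians of -0.18 to -0.13 for the ribosomal protein list, close to its own, and -0.15 to -0.04 for the respiratory chain list (central 95%). These random lists could draw members of the list itself. With deposited TPM the median of all genes was 0.10 at 24 h, and these medians lay nearer to 0, at -0.21 for G1/S, -0.07 for G2/M, -0.09 for ribosomal protein, -0.10 for respiratory chain and -0.04 for ribosome biogenesis genes. The reference gene list was also lower, at -0.12 (percentile 2.24, 12.4 with length and GC matching, and not apart with FPKM or TPM), with HPRT1 at -0.42 and GUSB at -0.39. The length trend across genes had a rho of 0.31 at 24 h, but of 0.08 for 24 h against 6 h, where the 0 h library is not used.

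**Figure D2:**
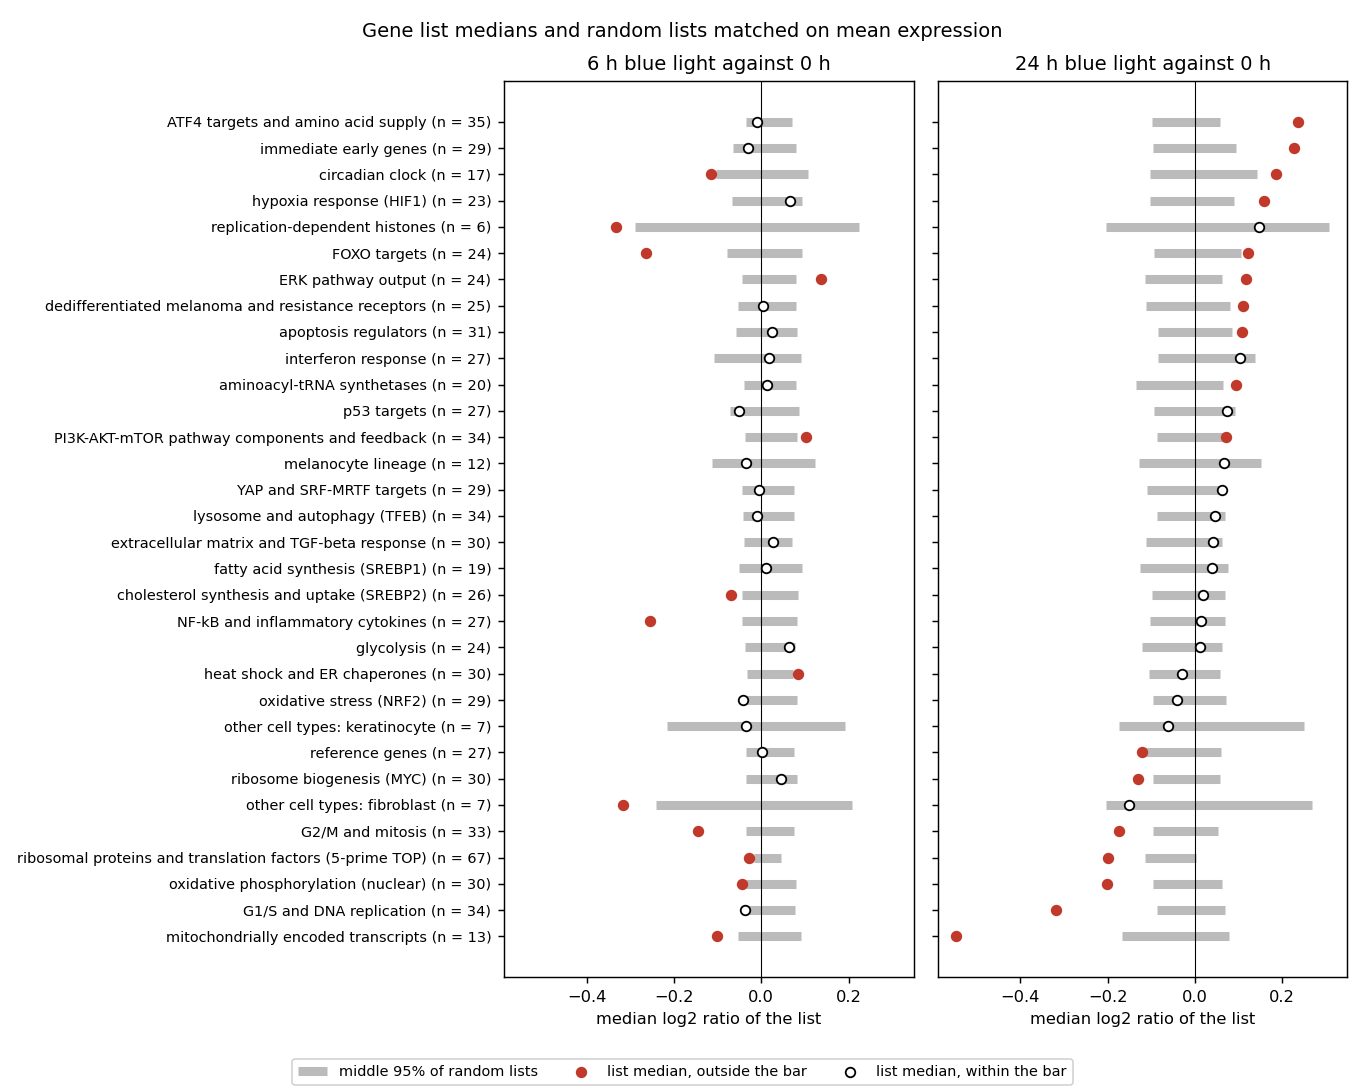
Each row is a gene list with its number of measured members, and the x axis gives its median log2 ratio to the 0 h library at 6 h and at 24 h. Grey bars span the central 95% of random lists matched on mean expression, and filled points lie outside them. At 24 h the ATF4 targets lie highest (0.24) and the mitochondrially encoded transcripts lowest (-0.55).

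At 24 h 17 lists lay outside the central 95%, 10 above and 7 below. FOXO targets stood above, with a median of 0.12 (percentile 98.7), a call lost with no expression filter and at a mean of at least 5 CPM. Circadian clock genes had a median of 0.19 (99.6), with PER1 and NR1D1 at 0.38 and CRY1 at -0.45. The ERK output list had 0.12 (99.9), with LIF at 0.41, and apoptosis regulators 0.11 (99.5), with BIRC3 at 0.56; the latter call was lost with FPKM and TPM. The PI3K component list (0.07, percentile 97.9) and the dedifferentiated melanoma list (0.11, percentile 99.5) lost the call with length and GC matching, at percentiles 70.1 and 94.1. JUN, a member of the latter list too, was its single gene past the size rule. The NF-kB and cytokine list stood at 0.01 (79.2) at 24 h, with IL24 above and CXCL1 at -0.85. Lower by the size rule at 24 h were CHML, a Rab escort protein gene (22.1 to 10.0 CPM), FDCSP (log2 ratio -1.09), ACAP1 (-1.05) and CCDC144NL (-1.02).

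Genes fixed by name for their known link to PI3K, MAP kinase or melanocyte identity stayed within 1.5-fold at both times, apart from TXNIP. In CPM at 0, 6 and 24 h, CCND1 stood at 795, 925 and 753 and MYC at 12.5, 12.4 and 15.9. IRS2 stood at 67.9, 62.4 and 72.0, SGK1 at 42.9, 50.9 and 33.1, and TNFAIP8 at 26.2, 21.9 and 24.0. DUSP6 stood at 273, 312 and 286 and MITF, the melanocyte master regulator, at 22.8, 17.6 and 22.0. PIK3IP1, a negative regulator of PI3K, had 14, 12 and 16 reads, and its ratio at 6 h of 0.842 (0.356 to 1.96) leaves a difference undetectable at this depth. TXNIP at 24 h stood at 95.3 CPM, a ratio of 1.64 (1.56 to 1.73).

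The comparison of 24 h with 6 h of light showed which values moved on between the lit libraries. EGR1 (41.4 to 156 CPM), TXNIP (25.9 to 95.3), IL24 (35.2 to 118), GDF15 (11.1 to 31.4) and INHBE (log2 ratio 1.36) were higher. HSPA1A (84.3 to 36.5 CPM), HSPA1B (3094 to 1652 reads), ACAP1 (-1.62), PIGY (-1.21) and TNFSF14 (-1.14) were lower. FOXO targets had a median of 0.30 (percentile 100, 20 of 24 above), NF-kB and cytokine genes 0.30 (100), G1/S genes -0.30 (0.0) and heat shock and ER chaperone genes -0.16 (0.06, 28 of 30 below). Of the 32 lists 18 lay outside the central 95%, 12 above and 6 below. The others above were histones (0.43), ATF4 targets (0.25), clock genes (0.23), immediate early genes (0.14), p53 targets (0.11), cholesterol synthesis (0.08), aminoacyl-tRNA synthetases, ERK output and lysosome genes (0.05 each) and extracellular matrix (0.04). The others below were mitochondrially encoded transcripts (-0.34), ribosome biogenesis (-0.20), ribosomal proteins (-0.16) and nuclear respiratory chain genes (-0.13). Reference genes stood at -0.13 too, with 25 of 27 below, and narrowly within the limit at percentile 2.94. Genes with a higher mean CPM had lower ratios here (Spearman rho -0.22 across 13507 genes), and the random lists were matched on mean expression. The histone call was lost with no filter and at a mean of at least 5 CPM, the ERK call at 5 CPM, and those of extracellular matrix, ribosomal protein and respiratory chain genes with length and GC matching.

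**Figure D3:**
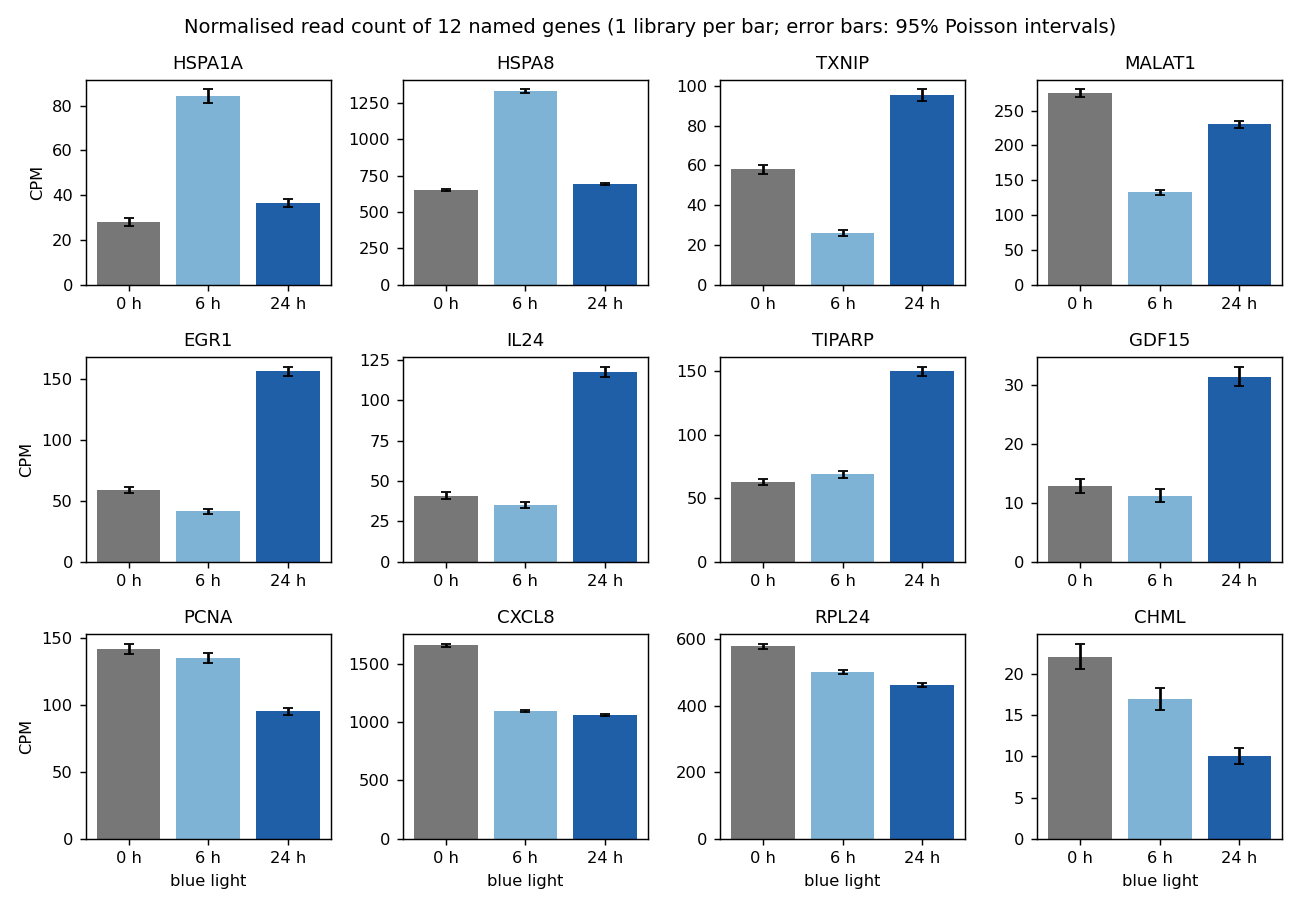
Normalised read count in CPM of 12 named genes after 0, 6 and 24 h of blue light, with 1 library per bar and 95% Poisson intervals as error bars. HSPA1A and HSPA8 stand highest at 6 h (84.3 and 1331 CPM), TXNIP lowest at 6 h (25.9), and EGR1, IL24, TIPARP and GDF15 highest at 24 h.

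Readthrough genes, annotated for transcripts that join neighbouring genes, held the extreme ratios. Of 88 measured, 8 were higher and 13 lower by the size rule at 6 h, and 12 and 8 at 24 h. BLOC1S5-TXNDC5 went from 2229 reads at 0 h to 10 at 6 h and 37 at 24 h, and its component genes together from 180 to 236 and 208 CPM. At 6 h ARHGAP11A-SCG5 (-4.45), TVP23C-CDRT4 (-4.17), SENP3-EIF4A1 (-3.95) and COMMD3-BMI1 (-3.75) followed. HSPE1-MOB4 (-1.88), ATP5MF-PTCD1 (-1.77), RTEL1-TNFRSF6B (-1.63) and JMJD7-PLA2G4B (-1.39) were lower too. ISY1-RAB43 (2.98), POC1B-GALNT4 (2.40), SERF2-C15ORF63 (2.17), MSANTD3-TMEFF1 (1.43) and SEPT5-GP1BB (1.06) were higher, as were the components CDRT4 (1.54) and CPT1B (1.01). At 24 h SENP3-EIF4A1 (-4.25), ARHGAP11A-SCG5 (-3.77), RAB4B-EGLN2 (-2.11), CHKB-CPT1B (-1.69) and FMC1-LUC7L2 (-1.26) were lower. POC1B-GALNT4 (2.05), RPL36A-HNRNPH2 (1.87), MSANTD3-TMEFF1 (1.41), PTGES3L-AARSD1 (1.35), CPT1B (1.34) and ISY1-RAB43 (1.33) were higher. Between 24 h and 6 h TVP23C-CDRT4 stood at 4.39 and COMMD3-BMI1 at 3.15, and ISY1-RAB43 at -1.65, BIVM-ERCC5 at -1.57, RAB4B-EGLN2 at -1.46 and CHKB-CPT1B at -1.24. Without readthrough genes and their components, 25 genes were higher and 27 lower at 6 h, and 40 and 12 at 24 h.

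Against the shared 0 h library, 17 genes were higher at both times and 7 lower, and none went opposite ways. Independent lists would share 0.14 and 0.06 genes. Unchanged simulated libraries shared 0.0 genes with a coefficient of variation of 0.1 and 25.1 with 0.2. The value of 0.2, set for every gene, also gave more calls at 6 h than were observed. Readthrough genes or their components made up 9 of the 17 and 6 of the 7. CCDC144NL, annotated as a transcribed pseudogene, was lower at both times. PAK6, UTP14C, IL19 and ZFHX2 were among those higher, named here after their values were seen. Reads shared with overlapping or related genes outside the listed readthrough loci were not examined for these genes. The single control library cannot be split, so part of the excess may come from it.

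In the authors' deposited table, 8 genes had an adjusted p-value under 0.05 at 6 h, of which 7 were readthrough genes and 1 a component of one. At 24 h it listed 6, of which 3 were readthrough genes and 1 a component, and the other 2 were the ribosomal protein pseudogene RPL41P3 and GREM1, which had a mean below 1 CPM. Both are named after their values were seen, and reads of a pseudogene can be shared with its parent gene. The p-values of the authors' deposited table equal an exact test with an assumed coefficient of variation of 0.4, so they do not rest on replicates.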

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

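The tests of whole-locus change and read assignment, the size limit in the latter, and the choice of length and GC matching and of the extra heat shock list, were made after the pattern had been seen.

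FOXO targets had a median log2 ratio of -0.26 at 6 h and 0.12 at 24 h, both apart from random lists and of opposite sign. Circadian clock genes did likewise, with -0.12 and 0.19. With 1 library per time, neither difference was tested. The FOXO call at 24 h was lost with no filter and at a mean of at least 5 CPM, and the clock call at 6 h with no filter, FPKM or TPM.

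Readthrough genes led the ratios in both comparisons with 0 h. A change of at least 2-fold in transcription of the whole locus was argued against, as 0.0% of 41 merged entries (readthrough gene plus components) stayed past 2-fold. Smaller changes of a locus stay open. A locus was entered once per time, so those called at both times, such as BLOC1S5-TXNDC5, are repeated against the same 0 h library. The 41 entries are therefore not independent. Over all 41 the components moved the opposite way in 35, and in 95.7% (22 of 23) of those where the change of the readthrough gene was, by a limit on its size, large enough to show in them. Only the direction was scored, and the amounts varied at 6 h. TVP23C-CDRT4 went from 11.3 to 0.16 CPM and its components from 15.7 to 28.1. ARHGAP11A-SCG5 went from 17.4 to 0.32 CPM, but its components only from 128 to 132. The opposite directions fit reads being assigned to a readthrough gene in 1 library and to its components in another. A candidate explanation is therefore the assignment of shared reads, but a real switch between transcripts of the locus would look alike and stays open.

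Ribosomal protein, replication and respiratory chain lists were lower at 24 h. Transcript length and GC content, as matched, do not account for the whole of it in replication and respiratory chain genes, both at percentile 0.0 of matched random lists. Ribosomal protein genes lay at percentile 0.18, but the matched lists themselves had medians of -0.18 to -0.13. Those lists could draw ribosomal protein genes too. How much of the -0.20 is shared with other genes of like length and GC content therefore cannot be told. The nearest genes used in matching need not be of equal length, so length as the whole cause was not excluded for ribosomal protein genes. Time in reduced serum cannot be told apart from light, because no dark library kept as long in reduced serum was analysed here. PI3K activation by light, which the design names, stays open as untested.

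Heat shock genes were higher at 6 h. A split of shared reads between HSPA1A and HSPA1B leaves their sum unchanged. The sum had a ratio of 3.02 (2.87 to 3.18), which argues against that split as the source of their rise. Other heat shock factor targets cannot bear on the split. Outside the fixed lists, these targets lay at percentile 99.94 (median 0.16, 13 of 16 above 0). The same value is consistent with a heat shock factor response, as a hypothesis. What would trigger it was not tested: light, warming, handling and reduced serum all differ between the libraries or are not recorded in the sources used here.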

How the results depend on the processing

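Settings that handle readthrough genes and the length and GC matching were chosen after the data were seen. No paired analysis was possible because each group had 1 library. No ratio of a named gene past the size rule and no list median apart from random lists changed sign, but the excess of higher over lower genes at 24 h (55 and 21) was absent with FPKM (22 and 23) and at 3-fold (10 and 10). All 7 counts of genes (higher and lower at 6 h, at 24 h and for 24 h against 6 h, then shared by both times) stayed within 1.5 times their main values of 36, 43, 55, 21, 69, 28 and 24 with DESeq2 size factors, plain CPM and no filter. In that order they were 12, 18, 20, 10, 23, 13 and 11 at a mean of at least 5 CPM, and 62, 87, 92, 32, 131, 49 and 38 with a pseudocount of 0.1. A pseudocount of 2 gave 13, 17, 25, 9, 19, 13 and 7. A limit of 1.5-fold gave 211, 287, 320, 137, 490, 156 and 116, and 3-fold gave 8, 11, 10, 10, 10, 6 and 6. These follow from how each setting admits low or small changes. Deposited FPKM gave 15, 34, 22, 23, 18, 13 and 11. Deposited TPM gave 85 lower at 6 h, 85 and 49 at 24 h, 105 higher for 24 h against 6 h, and 39 shared; the cause was not tested. Leaving out readthrough genes and components, or merging them, each gave 27 lower at 6 h, 12 lower at 24 h and 9 shared, since they hold many of the calls. Under alternatives 815 list medians kept their call and 40 did not, 13 of them with FPKM and 12 with TPM. With TPM the medians of lists at 24 h against 0 h, except that of histones, were higher, as was the median of all genes (0.10). Of 96 list percentiles, 11 changed their call with length and GC matching, of which p53 targets at 24 h (98.0) and hypoxia genes at 24 h against 6 h (97.7) gained one. Of 798 log2 ratios of named genes, 126 moved by more than their counting interval, mostly with FPKM (56), TPM (43) or a pseudocount of 2 (20). Judged by whether they lay inside the interval of the ratio without a pseudocount, 204 did not; the former reading was adopted after both were seen. The alternative of summing genes that share a symbol was not run, as no symbol is shared. Depth limits the low genes: PIK3IP1, with 14 and 12 reads at 0 and 6 h, had a counting interval of 0.356 to 1.96 for its ratio.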

Other observations

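The gene groups in this part, and the choice to test them, followed a look at the ratios.

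The chaperone list was split by compartment after the ratios were seen. Its 13 cytosolic and mitochondrial members had a median log2 ratio of 0.49 at 6 h (10 above 0) and -0.03 at 24 h. They include HSPA1A, HSPA1B and HSPA8, the genes past 2-fold that prompted the split, so their median at 6 h restates that observation. The 17 members of the endoplasmic reticulum had medians of 0.03 at 6 h (12 above 0) and -0.03 at 24 h. At 24 h against 6 h all 13 of the former were below their 6 h level, with a median of -0.30. Of the latter 15 were below, with a median of -0.13 at percentile 4.03, not apart from random lists.

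CYP1A1, CYP1B1 and TIPARP, known targets of the aryl hydrocarbon receptor, were higher at 24 h. CYP1A1 had 77 reads at 0 h, 126 at 6 h and 420 at 24 h, a ratio of 4.57 (3.57 to 5.90) at 24 h. A receptor response may be a hypothesis here, but 11 other targets had a median of 0.08 at percentile 86.94 (7 above 0, 4 below), and at 90.14 with length and GC matching. The test was to argue against the response at or below percentile 90, a bound met by the former and narrowly missed by the latter. Since the members also went both ways, the result was read as undecided, a reading adopted after the value was seen.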
